A study of Mus musculus with 6 samples.

How the data were processed

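Aortic roots of C57BL6/J mice labelled Sost+/+ (3 libraries, called WT 1 to 3 by replicate) or Sost-/- (3 libraries, called KO 1 to 3) were profiled by RNA sequencing after snap freezing, Trizol extraction and a directional library kit, per the labels' protocols. The labels speak of 3 roots in each group and do not name animals, so p-values measure the spread between these roots. Replicates were numbered in accession order and are not paired. Samples were placed in groups by the genotype label alone.

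The deposited table of counts holds whole-number read counts for 23420 gene symbols, of which 3648 were 0 in every library. The submitters' processing notes name DRAGEN, HTSeq, DESeq2 and the build mm10. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes may therefore not be told apart, and paralogs may share reads. The deposited table of normalized signal holds the same counts divided by 1 factor per library, and these factors equalled DESeq2's size factors computed here from the counts. Mitochondrially encoded genes were not analysed here.

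Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 15096. Libraries were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. Fold changes are KO against WT. The common biological coefficient of variation was 0.141. Total counts were 48172863, 40756468 and 37023586 in WT 1 to 3, and 41803775, 38870673 and 39365312 in KO 1 to 3. CPM refers to TMM-scaled library sizes. The top gene, Myh6, took 2.41% to 3.58% of counts, and the 10 top genes took 11.8% ± 0.41 (SD, n = 3) in WT and 9.36% ± 0.72 (SD, n = 3) in KO libraries.

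The designs, the 48 gene lists (26 of function and 22 of cell types), the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The rule names Sost, the 12 largest rises and 12 largest falls with adjusted p under 0.05, mean CPM of at least 1 and no overlap between groups, and up to 4 members of smallest p per list, passing over gene models without a name. Of the 200 genes it gives, 86 were taken for the text: of each list the members that passed or, where none did, the 1 of smallest p. Of these, 3 are not reported here. The narrowing was made after the values were seen. Older symbols were matched through RefSeq synonyms, also decided after a first run of the lists, and 8 list genes were matched in this way, among them Gm129, an older symbol of the clock gene Ciart. Of 982 list genes, 955 were in the table and 877 were measured.

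Lists were tested with limma 3.58.1, by camera on log2 CPM (prior count 2, preset correlation 0.01) for 46 lists with at least 5 measured members, by camera with the correlation estimated per list, and by fry. The lists of mitochondrially encoded genes (0 measured) and of thyroid and parathyroid markers (3 measured) were not tested. Beside the count over all genes, each list has a count adjusted over the list alone. Coordinates come from GENCODE M21 (GRCm38, the assembly of mm10) for 21737 genes and from RefSeq for a further 248 by symbol and 1297 by synonym, and 15050 of the tested genes had coordinates (99.7%). Location was tested with Fisher's exact test, two-sided, in windows of 10, 5 and 20 Mb around Sost. Single measures were compared by exact two-sided permutation tests over the 6 libraries.

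Alternatives were other scaling factors, filters, tests (DESeq2 1.42.0, limma-voom, voom with library weights), robust dispersion, covariates for cell type scores, scaling without muscle genes, the deposited normalized values with a pseudocount of 1, and each library left out. The smooth muscle covariate, and DESeq2 and limma-voom with a library left out or with that covariate, were added after seeing the data. No pair of libraries was alike within sampling noise: the chi-square per degree of freedom ran from 34.1 to 170. The edgeR step was tested on simulated data for this comparison over 15096 genes: 28.8%, 82.1% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and 11 of 152 calls were false. The list step, run on the 46 lists with simulated counts, called the 1 planted list and 0 others. Genes were simulated independently there, whereas the estimated correlation within the real lists reached 0.86. The simulation therefore cannot show how often camera calls correlated lists falsely.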

Results

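RNA from 6 aortic roots of C57BL6/J mice was measured by bulk RNA sequencing, 3 labelled Sost+/+ and 3 labelled Sost-/-. The aortic root is the first part of the aorta, which carries the aortic valve and borders on heart muscle. The mice were 12 months old and had received a high-cholesterol diet for 8 months, from 4 months of age. Counts summed over genes were 48172863, 40756468 and 37023586 in the libraries labelled Sost+/+, and 41803775, 38870673 and 39365312 in those labelled Sost-/-. The comparison asks how loss of Sost changes expression in the root under conditions that promote calcific valve disease.

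Sost encodes sclerostin, a secreted antagonist of Wnt signalling, and lies on chromosome 11 from 101962458 to 101967015 on the minus strand (build mm10, gene ENSMUSG00000001494.6 in GENCODE M21). Its counts were not lower in the libraries labelled Sost-/-. The libraries labelled Sost+/+ held 354, 621 and 274 Sost counts, and those labelled Sost-/- held 2284, 1063 and 513. The mean levels in CPM, counts scaled to library size, were 10.4 ± 4.66 (SD, n = 3) and 30.6 ± 20.9 (SD, n = 3), a log2 fold change of 1.56 (SE 0.48) that did not pass the test (edgeR adjusted p = 0.124, exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). The target gene therefore goes against the genotype labels, and every direction given here is for the libraries labelled Sost-/- against those labelled Sost+/+. Counts per gene cannot show whether the reads come from a part that the allele removes or from a part that it keeps.

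**Figure D1:**
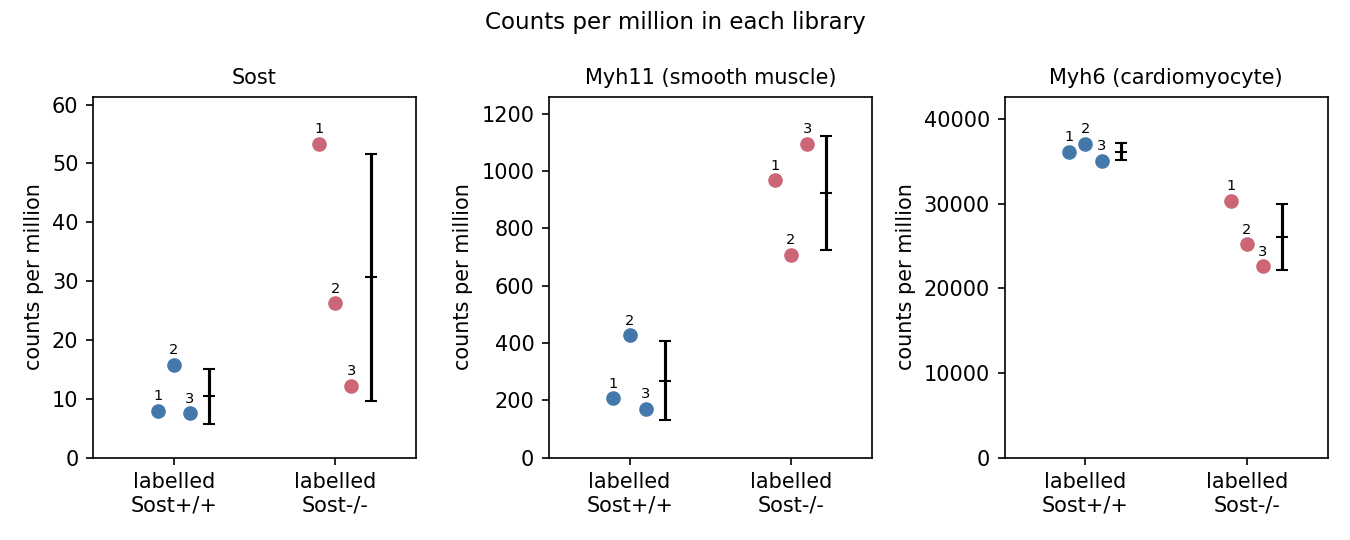
CPM (vertical axes, starting at 0) of Sost, the smooth muscle myosin gene Myh11 and the cardiomyocyte myosin gene Myh6 in each of the 6 libraries, numbered by replicate, with the group mean and SD as a bar beside the points. Sost in the libraries labelled Sost-/- is not lower than in those labelled Sost+/+, and Myh11 and Myh6 were chosen for the plot after their values were seen.

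In the libraries labelled Sost-/-, 329 genes rose and 56 fell. Among named genes with a mean CPM of at least 1, the largest rise was in Nxph1, which encodes a neurexophilin (log2 fold change 3.23, SE 0.33, adjusted p = 0.01003, from 0.202 ± 0.0391 to 1.90 ± 0.357 CPM, mean ± SD, n = 3), followed by the GABA-A receptor subunit gene Gabra3 (log2 fold change 2.92, SE 0.36, adjusted p = 0.0119, from 3.96 ± 2.58 to 30.1 ± 3.82 CPM) and by Vwc2, which encodes a secreted BMP antagonist (2.86, SE 0.35). Gabre, another GABA-A receptor subunit gene, rose by 2.62 (SE 0.37) on the log2 scale, and Itga8, the integrin alpha-8 subunit of smooth muscle, by 2.20 (SE 0.33). The cartilage proteoglycan gene Acan rose from 1.84 ± 1.14 to 8.44 ± 2.02 CPM (log2 fold change 2.20, SE 0.38, adjusted p = 0.0252). Stbd1, Susd5, Clec3a, Kcnc4, Kcnt1 and Igfbp2 also rose, with log2 fold changes of 2.33, 2.31, 2.13, 2.12, 2.10 and 2.08. None of these calls remained with a covariate for smooth muscle (the mean level of its markers without Sost, added after the results were seen). Nxph1, Kcnt1 and Clec3a were at 2.72, 2.89 and 1.95. Gabra3 1.11, Vwc2 1.09, Stbd1 0.73, Gabre 0.73, Itga8 0.24, Acan 0.23, Susd5 0.18, Kcnc4 0.13 and Igfbp2 -0.16 lay far lower. Itga8 is itself among the markers averaged for the smooth muscle covariate, so its fall there was largely fixed in advance. A covariate for cardiomyocytes moved most of them the other way, and calls stayed for Igfbp2 (5.12), Gabre (4.92), Acan (4.86), Susd5 (4.69) and Itga8 (4.37). Mean log2 CPM of the cardiomyocyte list was 11.18 to 11.36 in WT and 10.85 to 10.97 in KO libraries. That of the full smooth muscle list was 6.37 to 7.08 in WT and 7.54 to 7.92 in KO libraries. Neither score overlapped between the groups, so values with a covariate extrapolate beyond the libraries measured.

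Among such genes the largest fall was in Nppb, the natriuretic peptide gene of stressed heart muscle, from 547 ± 65.6 to 223 ± 76.3 CPM (mean ± SD, n = 3, log2 fold change -1.30, SE 0.21, adjusted p = 0.0235). Irx1, a transcription factor gene, changed by -1.24 (SE 0.17) on the log2 scale, and Abra, an actin-binding protein gene of muscle, by -1.05 (SE 0.16). Spon2, Tac1, Ube2j2, Tnfrsf12a and Acp1 fell as well, with log2 fold changes of -1.01, -0.94, -0.93, -0.90 and -0.85. The clock gene Arntl (-0.94), the stress-induced factor gene Atf3 (-0.91), the muscle calcium store gene Casq1 (-0.87) and the calcineurin regulator gene Rcan1 (-0.87) completed the 12 largest falls. These calls also ended with that covariate, where Spon2 (-1.17), Arntl (-0.98) and Irx1 (-0.93) were lowest, and Nppb was at -0.49, Abra at -0.22 and Rcan1 at 0.0049. The cardiomyocyte covariate kept only the call of Abra (-2.02), with Nppb at -2.26 and Rcan1 at -1.43. Nppb is itself among the markers averaged for the cardiomyocyte covariate, so its value there is not independent of that score.

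The test was edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment over 15096 genes, and 385 genes passed at 0.05. Each of the 385 had no overlap between the 3 libraries of either group, as had 3838 of the tested genes (25.4%, where chance gives 10%). DESeq2 called 1158 genes, 753 higher and 405 lower, and 65.0% of its calls were higher against 85.5% by edgeR. Without WT replicate 1, edgeR called 0 genes (2262 at an unadjusted p under 0.05), DESeq2 624 and limma-voom 0. Without KO replicate 3 these counts were 10 (1714 at an unadjusted p under 0.05), 364 and 45, while edgeR called 118 without WT replicate 3 and 218 without KO replicate 2. Voom with library weights called 582 genes. With a cardiomyocyte score as covariate edgeR called 40 genes, and with the smooth muscle score 0 (453 at an unadjusted p under 0.05), against 2 by DESeq2 and 0 by limma-voom.

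Most smooth muscle markers rose in the libraries labelled Sost-/-, and some cardiomyocyte markers fell. Of 20 measured smooth muscle markers, 12 rose and 0 fell (15 and 1 adjusted over the list alone), with a median log2 fold change of 1.28. This list also holds Sost, as well as Pln and Des, which are on the cardiomyocyte list too. Itga8, Myl9 (1.62, SE 0.26), Cnn1 (1.70, SE 0.28) and Kcnmb1 (2.06, SE 0.34), an integrin subunit, a myosin light chain, calponin and a potassium channel subunit, had the smallest p. Of 28 cardiomyocyte markers, 0 rose and 2 fell (0 and 16 adjusted over the list alone), with a median of -0.38. The members that fell were Nppb and the muscle LIM protein gene Csrp3 (-0.51, SE 0.11). Cardiomyocyte markers took 13.4% ± 0.14 (SD, n = 3) of counts in the libraries labelled Sost+/+ and 10.9% ± 0.83 (SD, n = 3) in those labelled Sost-/- (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). For smooth muscle, camera adjusted p was 2.34e-07, and adjusted p = 0.439 with an estimated correlation. For cardiomyocytes, camera adjusted p was 2.40e-09, and adjusted p = 0.439 with an estimated correlation. Without WT replicate 1 and without KO replicate 3, 0 smooth muscle markers passed in edgeR, and 1 passed without WT replicate 3. DESeq2 called 16 cardiomyocyte markers lower. The smooth muscle median was 2.45 with the cardiomyocyte covariate, and the cardiomyocyte median -0.31 with the smooth muscle covariate.

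**Figure D2:**
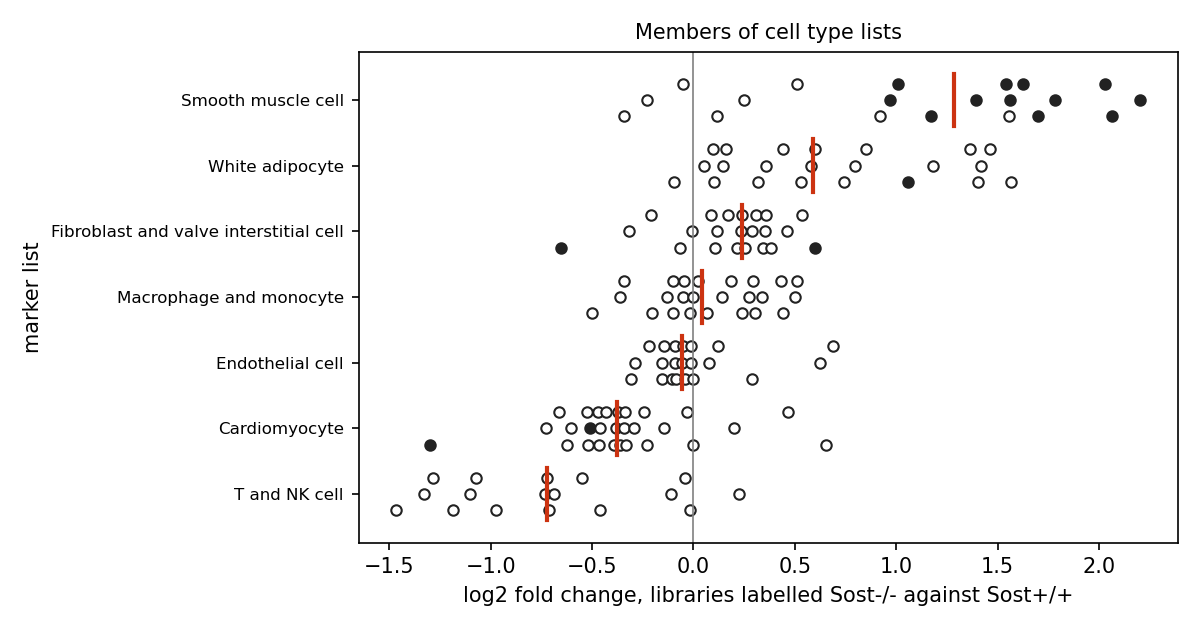
Log2 fold change (horizontal axis, libraries labelled Sost-/- against Sost+/+, n = 3 each) of each measured member of 7 cell type lists (vertical axis), with filled points for members past the gene test, open points for the others, and a red line at the list's median. The smooth muscle median lies at 1.28 and the cardiomyocyte median at -0.38.

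Clock genes moved in both directions. Of 18 measured circadian clock genes, 7 rose and 2 fell (10 and 3 adjusted over the list alone). Per3, a clock gene of the Period family, rose from 22.0 ± 2.04 to 57.6 ± 6.63 CPM (log2 fold change 1.39, SE 0.11, adjusted p = 0.00735). The clock output factors Dbp (1.17, SE 0.11) and Tef (0.85, SE 0.11) rose as well. Arntl, the gene of the core activator BMAL, fell from 23.1 ± 1.22 to 12.0 ± 1.37 CPM (log2 fold change -0.94, SE 0.11, adjusted p = 0.0119). For the clock list, camera adjusted p was 0.0102, and adjusted p = 0.439 with an estimated correlation. Its members went both ways. Without WT replicate 1, 0 clock genes passed in edgeR, and without KO replicate 3, 3 passed, all higher. Both covariates ended the gene calls of this list, with 0 and 0 called. Values with the smooth muscle and the cardiomyocyte covariate were, in that order, Per3 0.998 against 1.60 and Dbp 1.19 against 1.02. Tef was at 0.86 against 0.62 and Arntl at -0.98 against -0.66. Per2, also called without a covariate, went from 1.17 to 0.41 with the smooth muscle covariate. The list median was 0.30 (camera adjusted p = 0.254) against 0.55 (adjusted p = 0.00554). Smooth muscle markers, median log2 fold change 1.28, and cardiomyocyte markers, median -0.38, differed in the same libraries.

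**Figure D3:**
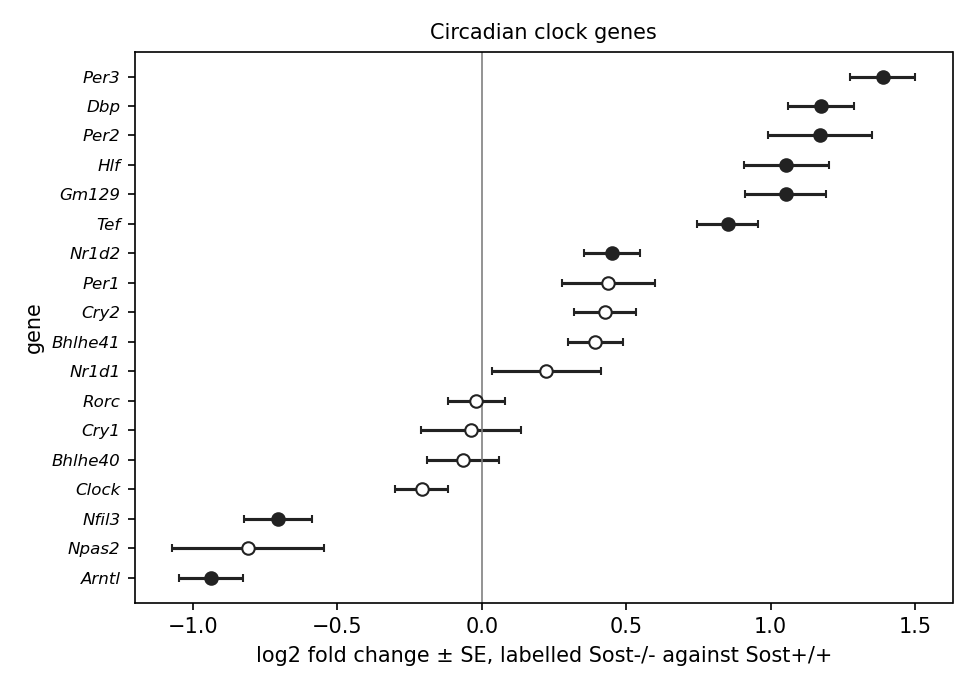
Log2 fold change with its SE (horizontal axis) of 18 measured circadian clock genes (vertical axis) in the libraries labelled Sost-/- against Sost+/+ (n = 3 each), with filled points for genes past the gene test. Per3 is at 1.39 and Arntl at -0.94, at opposite ends.

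Few Wnt and BMP pathway genes passed in edgeR, where 385 of all 15096 tested genes passed. Of 22 measured Wnt/beta-catenin target genes, 1 rose and 0 fell (4 and 0 adjusted over the list alone), and the member that rose was the feedback inhibitor gene Nkd1 (log2 fold change 1.07, SE 0.18, adjusted p = 0.0247). Of 36 Wnt ligands, receptors and secreted antagonists, 3 rose and 0 fell (6 and 0 adjusted over the list alone): the antagonist Sfrp4 (1.42, SE 0.22) and the ligands Wnt5a (0.56, SE 0.10) and Wnt16 (1.05, SE 0.22). Of 25 BMP genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone), among them the receptor Bmpr1b (1.66, SE 0.23) and the BMP antagonist Chrdl1 (0.98, SE 0.17). Of 25 TGF-beta genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone), with Ltbp1 (0.68, SE 0.14) and Ltbp3 (0.48, SE 0.10) higher and Cdkn1a (-0.77, SE 0.12) lower. Of 16 Notch genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone), Jag1 (0.57, SE 0.09) and Hey2 (1.33, SE 0.22). For the Wnt targets, camera adjusted p was 0.00760, and adjusted p = 0.590 with an estimated correlation. For Wnt ligands and antagonists, camera adjusted p was 0.000343, and adjusted p = 0.439 with an estimated correlation. For BMP genes, camera adjusted p was 0.000322, and adjusted p = 0.439 with an estimated correlation. The test did not call TGF-beta genes and Notch genes (camera adjusted p = 0.122 and 0.549). Higher and lower members called by DESeq2 were: Wnt targets 4 and 0, Wnt ligands and antagonists 7 and 0 and BMP genes 7 and 0. The 2 covariates moved values in opposite directions, with the smooth muscle covariate first: Nkd1 0.10 against 2.23, Chrdl1 0.44 against 1.76, Ltbp1 0.10 against 1.26, Ltbp3 0.29 against 0.82, Cdkn1a -1.12 against -0.14, Hey2 0.58 against 2.73, Wnt5a 0.47 against 0.87. The first ended every gene call, and the second kept those of Nkd1 and Hey2 here. List medians, in the same order, were: Wnt targets 0.17 (camera adjusted p = 0.471) against 0.53 (adjusted p = 0.00840), Wnt ligands and antagonists 0.11 (camera adjusted p = 0.521) against 0.43 (adjusted p = 0.000520), TGF-beta genes 0.10 (camera adjusted p = 0.778) against 0.43 (adjusted p = 0.00399), Notch genes 0.06 (camera adjusted p = 0.853) against 0.35 (adjusted p = 0.0164). TGF-beta genes numbered 0 and 1 higher and lower without KO replicate 1 and 1 and 0 without KO replicate 2, and Wnt ligands 1 and 0 without KO replicate 1. Smooth muscle markers, median log2 fold change 1.28, and cardiomyocyte markers, median -0.38, differed in the same libraries.

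Among skeletal and mineralization genes, single members passed in edgeR. Of 20 osteoblast and mineralization genes, 1 rose and 0 fell (5 and 2 adjusted over the list alone), and the member that rose was the keratan sulfate proteoglycan gene Omd (0.91, SE 0.18). Of 19 chondrocyte genes, 1 rose and 0 fell (3 and 1 adjusted over the list alone), namely Acan. Of 14 calcification inhibitors, 1 rose and 1 fell (3 and 1 adjusted over the list alone): Mgp, the gene of matrix Gla protein, rose from 769 ± 38.1 to 1191 ± 194 CPM (log2 fold change 0.63, SE 0.14, adjusted p = 0.0484), and Nt5e, an ectonucleotidase gene, was lower (log2 fold change -0.65, SE 0.13, adjusted p = 0.0410). Leaving out 1 library changed this count in every case: 3 and 0 were higher and lower without KO replicate 1, 0 and 1 without WT replicate 2 or KO replicate 2, and 0 and 0 without any of the others. Of 8 osteocyte genes, a list that also holds Sost, 2 rose and 0 fell (5 and 1 adjusted over the list alone): Kcnma1 (1.21, SE 0.14) and Ptprz1 (1.17, SE 0.17). For chondrocyte genes, camera adjusted p was 0.0467, and adjusted p = 0.590 with an estimated correlation. For osteocyte genes, camera adjusted p was 0.00918, and adjusted p = 0.439 with an estimated correlation. The test did not call osteoblast genes and calcification inhibitors (camera adjusted p = 0.130 and 0.180). DESeq2 called more, higher and lower: osteoblast genes 5 and 1, chondrocyte genes 4 and 1, calcification inhibitors 2 and 1 and osteocyte genes 3 and 1. No gene call here but that of Acan stayed with the cardiomyocyte covariate, and none with the smooth muscle covariate. Nt5e was at -0.09 with the smooth muscle and -1.19 with the cardiomyocyte covariate, and Ptprz1 at 0.74 and 1.48. In the same order Mgp was at 0.63 and 0.51, Omd at 0.77 and 0.88, Kcnma1 at 0.97 and 1.43 and Acan at 0.23 and 4.86. List medians, in that order, were: osteoblast genes 0.09 (camera adjusted p = 0.558) against 0.52 (adjusted p = 0.0461), chondrocyte genes 0.23 (camera adjusted p = 0.440) against 0.49 (adjusted p = 0.0357), calcification inhibitors 0.10 (camera adjusted p = 0.853) against 0.46 (adjusted p = 0.142), osteocyte genes 0.21 (camera adjusted p = 0.254) against 1.46 (adjusted p = 0.0425). Smooth muscle markers, median log2 fold change 1.28, and cardiomyocyte markers, median -0.38, differed in the same libraries.

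Matrix genes that passed in edgeR were higher. Of 33 collagen, elastin and proteoglycan genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone): Col14a1 (0.59, SE 0.09), Fbln5 (0.90, SE 0.14), Col18a1 (1.66, SE 0.27) and Ogn (0.54, SE 0.09). Of 31 matrix remodelling genes, 2 rose and 0 fell (6 and 2 adjusted over the list alone), the metalloproteinases Mmp3 (log2 fold change 1.69, SE 0.19, adjusted p = 0.0119) and Mmp9 (1.19, SE 0.17). Of 29 NADPH oxidases and antioxidant enzymes, 1 rose and 0 fell (2 and 0 adjusted over the list alone), and Nox4, an oxidase gene, went from 15.3 ± 2.67 to 42.0 ± 4.39 CPM (log2 fold change 1.46, SE 0.13, adjusted p = 0.01003). Of 14 senescence genes, 1 rose and 1 fell (3 and 2 adjusted over the list alone), Igfbp5 (0.70, SE 0.12) higher and Cdkn1a lower. For matrix genes, camera adjusted p was 0.0246, and adjusted p = 0.613 with an estimated correlation. The test did not call remodelling genes, oxidases and senescence genes (camera adjusted p = 0.344, 0.344 and 0.392). By DESeq2 the higher and lower members were: matrix genes 8 and 0, remodelling genes 5 and 2, oxidases and antioxidant enzymes 2 and 1 and senescence genes 3 and 1. Smooth muscle and cardiomyocyte covariates moved some values apart, in that order: Col18a1 0.14 against 3.58, Fbln5 0.21 against 1.77, Mmp9 0.48 against 1.77. Nox4 was at 0.77 against 2.17 and Mmp3 at 1.38 against 2.01. Col14a1 was at 0.44 against 0.81, Igfbp5 at 0.67 against 0.95 and Ogn at 0.46 against 0.42. The smooth muscle covariate ended every call, and the cardiomyocyte covariate kept those of Fbln5, Col18a1 and Nox4 here. The matrix list median was 0.11 and 0.43. Smooth muscle markers, median log2 fold change 1.28, and cardiomyocyte markers, median -0.38, differed in the same libraries.

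No member of the inflammatory, interferon, antigen presentation or foam cell lists passed in edgeR. Of 35 inflammatory genes 0 rose and 0 fell (0 and 0 adjusted over the list alone), with Il1r1 (0.24, SE 0.08) of smallest p, and of 24 interferon-stimulated genes 0 rose and 0 fell (0 and 0 adjusted over the list alone), with Bst2 (-0.41, SE 0.15). Of 21 MHC class II and complement genes 0 rose and 0 fell (0 and 0 adjusted over the list alone), and of 23 lipid and foam cell genes 0 rose and 0 fell (1 and 0 adjusted over the list alone), with Abca1 (0.38, SE 0.08). The test did not call inflammatory genes, interferon-stimulated genes, MHC class II and complement and foam cell genes (camera adjusted p = 0.583, 0.328, 0.845 and 0.669). DESeq2 called 2 MHC class II and complement genes and 2 foam cell genes higher, and without KO replicate 1 edgeR called 1 foam cell gene higher. List medians moved in opposite directions with the smooth muscle and the cardiomyocyte covariate, in that order: inflammatory 0.44 (camera adjusted p = 0.0227) against -0.33 (adjusted p = 0.268), interferon-stimulated 0.88 (camera adjusted p = 5.78e-11) against -0.70 (adjusted p = 0.0134), MHC class II and complement 0.51 (camera adjusted p = 0.00407) against -0.53 (adjusted p = 0.0853), foam cell genes 0.25 (camera adjusted p = 0.0902) against -0.23 (adjusted p = 0.142). No direction is drawn from either. In simulated data of this size, 28.8% of genes changed by 0.5 on the log2 scale were recovered, so smaller differences can go uncalled here.

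Few metabolic and stress genes passed in edgeR, and more in DESeq2. Of 45 nuclear-encoded oxidative phosphorylation genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), although all 45 had fitted values below 0 (median -0.34), with Ndufv1 (-0.46, SE 0.13) of smallest p. Of 24 unfolded protein response genes, 0 rose and 2 fell (0 and 13 adjusted over the list alone), Atf3 and Manf (log2 fold change -0.68, SE 0.11, adjusted p = 0.0204). Of 26 fatty acid oxidation genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a list median of -0.23 (-0.35 to -0.13 with 1 library left out, and 1 member called lower without WT replicate 3). Of 24 cholesterol synthesis genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with Lss (0.55, SE 0.20) of smallest p. Of 25 proliferation genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone), Cdc20 (-0.80, SE 0.16). Of 28 immediate early and heat shock genes, 0 rose and 2 fell (0 and 3 adjusted over the list alone), Atf3 and Hspa8 (-0.54, SE 0.11). Of 40 ribosomal protein genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with Rps2 (-0.38, SE 0.14) of smallest p. For oxidative phosphorylation, camera adjusted p was 6.40e-14, and adjusted p = 0.590 with an estimated correlation. For the unfolded protein response, camera adjusted p was 3.17e-06, and adjusted p = 0.439 with an estimated correlation. For fatty acid oxidation, camera adjusted p was 0.00136, and adjusted p = 0.613 with an estimated correlation. For cholesterol synthesis, camera adjusted p was 0.0371, and adjusted p = 0.439 with an estimated correlation. For proliferation genes, camera adjusted p was 0.000101, and adjusted p = 0.439 with an estimated correlation. The test did not call immediate early genes and ribosomal proteins (camera adjusted p = 0.0870 and 0.528). DESeq2 called 15 of 45 oxidative phosphorylation genes lower, 10 unfolded protein response genes, 4 fatty acid oxidation genes and 4 immediate early genes. Without WT replicate 3 edgeR called 3 oxidative phosphorylation genes lower. With the smooth muscle covariate camera called only oxidative phosphorylation and fatty acid oxidation of these lists. Medians with that and with the cardiomyocyte covariate were: cholesterol synthesis -0.027 (camera adjusted p = 0.841) against 0.24 (adjusted p = 0.0571), unfolded protein response -0.01 (camera adjusted p = 0.387) against -0.50 (adjusted p = 0.000140), proliferation -0.03 (camera adjusted p = 0.960) against -0.45 (adjusted p = 0.0291), fatty acid oxidation -0.26 (camera adjusted p = 0.00358) against -0.38 (adjusted p = 0.0997), oxidative phosphorylation -0.41 (camera adjusted p = 5.23e-10) against -0.57 (adjusted p = 1.42e-06), ribosomal proteins 0.08 (camera adjusted p = 0.841) against -0.49 (adjusted p = 3.06e-05), immediate early genes -0.10 (camera adjusted p = 0.190) against 0.42 (adjusted p = 0.349). No gene call stayed with either: Atf3 -0.47 against -1.15, Manf -0.58 against -1.11, Hspa8 -0.27 against -0.82, Cdc20 -0.72 against -0.86. Smooth muscle markers, median log2 fold change 1.28, and cardiomyocyte markers, median -0.38, differed in the same libraries.

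Of 22 fibroblast and valve interstitial markers, 1 rose and 1 fell (6 and 2 adjusted over the list alone), Vim (0.60, SE 0.12) and Nt5e. Of 22 white adipocyte markers, 1 rose and 0 fell (10 and 0 adjusted over the list alone), Scd1 (1.06, SE 0.19), with a median of 0.59. Of 20 Schwann cell and neuron markers, 1 rose and 0 fell (3 and 0 adjusted over the list alone), Prx (0.81, SE 0.17). Of 7 lymphatic endothelial markers, 1 rose and 0 fell (2 and 0 adjusted over the list alone), Mmrn1 (0.48, SE 0.10). Of 9 mast cell markers, 0 rose and 0 fell (5 and 0 adjusted over the list alone), with Cma1 (0.76, SE 0.20) of smallest p. Of 17 T and NK cell markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with Gzmb (-1.47, SE 0.45) of smallest p and a median of -0.72. Without WT replicate 3 the T and NK median was -0.36 and the camera call ended (adjusted p = 0.0782), so that library carries much of the value. For fibroblast markers, camera adjusted p was 0.0238, and adjusted p = 0.613 with an estimated correlation. For white adipocyte markers, camera adjusted p was 0.000143, and adjusted p = 0.609 with an estimated correlation. For Schwann cell and neuron markers, camera adjusted p was 0.00113, and adjusted p = 0.590 with an estimated correlation. For lymphatic markers, camera adjusted p was 0.0257, and adjusted p = 0.439 with an estimated correlation. For mast cell markers, camera adjusted p was 0.0279, and adjusted p = 0.609 with an estimated correlation. For T and NK cell markers, camera adjusted p was 0.00379, and adjusted p = 0.613 with an estimated correlation. The smooth muscle and the cardiomyocyte covariate gave medians, in that order, of: T and NK cell markers 1.05 (camera adjusted p = 1.12e-05) against -1.86 (adjusted p = 2.27e-06), mast cell markers -0.26 (camera adjusted p = 0.149) against 1.37 (adjusted p = 0.00391), fibroblast markers 0.11 (camera adjusted p = 0.242) against 0.22 (adjusted p = 0.263), white adipocyte markers 0.50 (camera adjusted p = 0.231) against 0.20 (adjusted p = 0.603), Schwann cell and neuron markers 0.05 (camera adjusted p = 0.983) against 0.39 (adjusted p = 0.0549), lymphatic markers 0.13 (camera adjusted p = 0.698) against 0.62 (adjusted p = 0.0721). No gene call stayed with either, with values of: Vim 0.31 against 0.93, Mmrn1 0.22 against 0.61, Prx 0.85 against 0.43. Fibroblast markers numbered 1 and 0 higher and lower without KO replicate 1 and 0 and 1 without KO replicate 2. Without KO replicate 1, 5 of 22 white adipocyte markers were called higher. Higher and lower members by DESeq2 were: fibroblast markers 6 and 2, white adipocyte markers 3 and 0, Schwann cell and neuron markers 4 and 0, lymphatic markers 2 and 0 and mast cell markers 3 and 0. Smooth muscle markers, median log2 fold change 1.28, and cardiomyocyte markers, median -0.38, differed in the same libraries.

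Camera did not call the remaining cell type lists, of which fry called neutrophil markers (fry adjusted p = 0.0279, higher). Of 21 endothelial markers 0 rose and 0 fell (0 and 0 adjusted over the list alone), with Tie1 (-0.29, SE 0.11) of smallest p and camera adjusted p = 0.247. Of 24 macrophage markers 0 rose and 0 fell (4 and 0 adjusted over the list alone), with Mertk (0.44, SE 0.10) of smallest p and camera adjusted p = 0.294. Of neutrophil markers, 1 of 6 rose and 0 fell (1 and 0 adjusted over the list alone), Mmp9. Of mesothelial markers, 1 of 14 rose and 0 fell (1 and 0 adjusted over the list alone), Efemp1 (0.75, SE 0.12), and of pericyte markers, 1 of 13 rose and 0 fell (3 and 0 adjusted over the list alone), Cspg4 (0.92, SE 0.17). Of skeletal muscle markers, 0 of 17 rose and 1 fell (0 and 2 adjusted over the list alone), Casq1. Camera adjusted p was 0.0829 for neutrophil, 0.141 for mesothelial, 0.450 for pericyte and 0.161 for skeletal muscle markers. Of B and plasma cell markers, 0 of 11 rose and 0 fell (1 and 0 adjusted over the list alone), with Ebf1 (0.42, SE 0.11) of smallest p. Of thymocyte markers, 0 of 5 rose and 0 fell (1 and 0 adjusted over the list alone), with Cd1d1 (0.98, SE 0.30). Of brown adipocyte markers, 0 of 15 rose and 0 fell (3 and 2 adjusted over the list alone), with Otop1 (2.11, SE 0.51), and of melanocyte markers, 0 of 10 rose and 0 fell (0 and 0 adjusted over the list alone), with Trpm1 (0.84, SE 0.35). Of airway markers, 0 of 5 rose and 0 fell (1 and 0 adjusted over the list alone), with Cyp2f2 (0.87, SE 0.27), and of erythrocyte transcripts, 0 of 7 rose and 0 fell (0 and 0 adjusted over the list alone), with Bpgm (-0.21, SE 0.12). Of sex-linked transcripts, 0 of 6 rose and 0 fell (0 and 0 adjusted over the list alone), with Tsix (-0.81, SE 0.44). Camera adjusted p was 0.679 for B and plasma cells, 0.364 for thymocytes, 0.679 for brown adipocytes, 0.143 for melanocytes, 0.247 for airway, 0.279 for erythrocytes and 0.344 for sex-linked transcripts. Without KO replicate 1, edgeR called 5 of 16 brown adipocyte and 2 macrophage markers higher, so these counts depend on that library. Higher and lower members by DESeq2 were: macrophage markers 4 and 0, brown adipocyte markers 2 and 2, pericyte markers 3 and 0, skeletal muscle markers 0 and 2, B and plasma cell markers 1 and 0, thymocyte markers 1 and 0 and airway markers 1 and 0. Medians with the smooth muscle and the cardiomyocyte covariate differed, in that order: endothelial -0.29 (camera adjusted p = 0.0227) against 0.37 (adjusted p = 0.0154), macrophage 0.53 (camera adjusted p = 2.06e-06) against -0.56 (adjusted p = 0.00540), erythrocyte -2.42 (camera adjusted p = 1.45e-09) against 1.85 (adjusted p = 0.00754), mesothelial -0.60 (camera adjusted p = 0.205) against 1.73 (adjusted p = 0.00840), pericyte -0.25 (camera adjusted p = 0.133) against 0.17 (adjusted p = 0.0229), skeletal muscle -0.45 (camera adjusted p = 0.00428) against -0.15 (adjusted p = 0.975). In the same order gene values were: Cspg4 0.13 against 2.06, Efemp1 0.42 against 1.14, Casq1 -0.35 against -1.79, and only the call of Cspg4 stayed, with the cardiomyocyte covariate. The thyroid list held 3 measured genes and no list test was run, with Tshr (1.16, SE 0.49) of smallest p.

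In all, camera called 20 of 46 lists, 14 higher and 6 lower, with a preset correlation of 0.01, and 0 with an estimated correlation. The fry test asks whether a list's genes move one way on balance and does not compare them with other genes. It called 9 lists, 8 of them among the 20. Higher among these 8 were Wnt ligands and antagonists, BMP, osteocyte, cholesterol synthesis and clock genes and lymphatic markers. Lower were unfolded protein response genes and cardiomyocyte markers. Their fry adjusted p ran from 0.0273 to 0.0478. Smooth muscle markers were not called by fry (fry adjusted p = 0.0527). With the smooth muscle covariate, of the 19 calls other than smooth muscle itself, 3 were kept in direction (oxidative phosphorylation, fatty acid oxidation and cardiomyocyte markers), 1 turned (T and NK cell markers) and 15 ended, while 7 further lists were called. With the cardiomyocyte covariate 13 of 19 calls other than cardiomyocytes were kept in direction, 6 ended and 10 were added. Leaving out 1 library ended camera calls of chondrocyte genes (4 of 6 libraries), cholesterol synthesis (3), matrix genes, fibroblast and mast cell markers (2 each), and lymphatic and T and NK cell markers (1 each). It also moved some medians by over 1.5 times: chondrocyte genes 0.23 to 0.46, matrix genes 0.11 to 0.22, proliferation genes -0.39 to -0.17, and fibroblast 0.14 to 0.33, white adipocyte 0.39 to 0.79, Schwann cell and neuron 0.28 to 0.52 and mast cell markers 0.36 to 0.80. Other splits of the 6 libraries into 3 against 3 also gave camera calls, from 8 to 23 lists.

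Within 10 Mb of Sost, 8 of 289 genes were called (2.77%), against 376 of 14760 elsewhere (2.55%), an odds ratio of 1.09 (95% interval 0.462 to 2.20, Fisher's exact test, two-sided p = 0.707). No chromosome passed after adjustment over chromosomes, the smallest adjusted p being 0.676. Meox1, a homeobox gene at 101877510 to 101894374 on the same chromosome and the nearest called gene to Sost, fell from 92.9 ± 1.43 to 57.8 ± 6.74 CPM (log2 fold change -0.68, SE 0.10, adjusted p = 0.0151), and was singled out after its values were seen.

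The first principal component of log2 CPM held 42.1% of the variance and separated the libraries by genotype label. Pearson's r across genes, which are not independent replicates, ran from 0.987 to 0.990 within a group and from 0.977 to 0.989 between groups.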

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

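The smooth muscle covariate, and the fits that join a left-out library or that covariate with DESeq2 or limma-voom, were chosen after the results had been seen. No paired analysis was possible because the labels give no replicate numbers, and those used here follow accession order. The 385 called genes kept their sign in 385 of 385 cases under RLE and upper-quartile factors, no filter, DESeq2, limma-voom, robust dispersion, library weights, the cardiomyocyte covariate, scaling without muscle genes, the deposited values, and without each library, and 362 did with the smooth muscle covariate. Under the strict filter 380 of them were tested and 380 kept it. Each of the 385 had no overlap between the groups, so a kept sign was nearly fixed in advance in fits without a covariate. The called count was 368 with RLE and 406 with upper-quartile factors, and stayed within 1.5 times of 385 under no filter (567, 92 lower against 56), the strict filter, limma-voom, robust dispersion, scaling without muscle genes and the deposited values.

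DESeq2 called 1158 genes (753 higher, 405 lower), and voom with library weights 582 (140 lower). The cardiomyocyte covariate left 40 genes (38 higher, 2 lower; 1681 at an unadjusted p under 0.05). The smooth muscle covariate left 0 in edgeR, 0 higher and 0 lower (453 at an unadjusted p under 0.05), 2 in DESeq2 (413) and 0 in limma-voom (433). Leaving out 1 library gave 0 to 349 genes, 0 to 313 higher and 0 to 37 lower: 0 without WT replicate 1, 118 without WT replicate 3, 218 without KO replicate 2 and 10 without KO replicate 3. Without WT replicate 1, DESeq2 called 624 and limma-voom 0 (2122 at an unadjusted p under 0.05), and without KO replicate 3 they called 364 and 45. Fewer samples and, under the covariates, a term tied to genotype widen the SE; other causes were not tested. Sost stayed above 0 and uncalled in all 18 alternatives, from 0.60 to 3.35, with adjusted p from 0.0567 to 0.9998.

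Camera called 11 lists with the smooth muscle covariate, 3 of them kept in direction, and 0 with an estimated correlation, and fry called 9, against 20. The list test under robust dispersion was not run, since camera takes no edgeR dispersion. With the cardiomyocyte covariate Tie1 reversed to 0.12, the medians of 8 of 46 tested lists changed sign, and for 3 of them, which camera called there, the test direction turned: 0.37 (endothelial), -0.56 (macrophage) and 1.85 (erythrocyte). With the smooth muscle covariate Igfbp2 reversed to -0.16, Rcan1 to 0.0049, Bst2 to 0.43 and Cyp2f2 to -0.31, 11 medians changed sign, and for 5 lists that camera called in either fit the test direction turned: 0.44 (inflammatory), 0.88 (interferon), -0.027 (cholesterol synthesis), 1.05 (T and NK cells) and -0.26 (mast cells). Without 1 library 2 to 6 medians changed sign. The odds ratio near Sost was 0.757 within 5 Mb and 0.671 within 20 Mb, on the other side of 1 from 1.09 within 10 Mb. The first component held 43.2% of variance with a prior count of 5 and 48.8% over the 500 most variable genes, against 42.1%. The cause of these changes was not tested.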

Other observations

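The gene families and smooth muscle genes below, the tests of marker lists against each other, of Sost against smooth muscle markers, of exchanged labels, of clock phases and of list calls over other splits were chosen after the results had been seen, and the conditions for Sost and for aortic wall were made stricter afterwards. Of 13 measured Hox genes, which encode positional transcription factors, 4 rose and 0 fell in the libraries labelled Sost-/-: Hoxa2 (1.59, SE 0.29), Hoxa3 (1.63, SE 0.30), Hoxa4 (2.28, SE 0.42) and Hoxb2 (1.40, SE 0.25), each with edgeR adjusted p under 0.05 (Fisher's exact p of the count = 0.000248, two-sided). All 13 had fitted values above 0, with a median of 1.04. The interval of Hoxa4 lies inside that of Hoxa3, so their values can rest on shared reads. Mean levels in WT and KO libraries were low: Hoxa2 0.665 and 2.02, Hoxa3 2.10 and 6.48, Hoxa4 0.297 and 1.46, Hoxb2 0.972 and 2.57 CPM. Of 5 measured GABA-A receptor subunit genes 3 rose, Gabra3 (2.92, SE 0.36), Gabre (2.62, SE 0.37) and Gabrq (3.76, SE 0.75), which lie together on chromosome X between 72255999 and 72842602 (Fisher's exact p = 0.000158). Gabrq is lowly expressed, at 0.0329 and 0.489 CPM. Of 6 Cd209 genes, lectin receptors of dendritic cells and macrophages, 4 rose: Cd209b (1.78, SE 0.26), Cd209d (1.40, SE 0.25), Cd209f (1.14, SE 0.21) and Cd209g (1.23, SE 0.22) (Fisher's exact p = 6.00e-06), although paralogs can share reads. The hedgehog targets Gli1 (0.92, SE 0.16) and Ptch1 (0.78, SE 0.16) rose, 2 of 4 (Fisher's exact p = 0.00376). Since the families were picked from the called genes, these p-values are not independent evidence. Smooth muscle markers, median log2 fold change 1.28, differed in the same libraries, and with their covariate edgeR called no gene. Gabra3 and Gabre were at 1.11 and 0.73 in that fit, against 4.64 and 4.92 with the cardiomyocyte covariate.

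Some called genes outside the fixed list have known roles in smooth muscle, and were picked from the called genes without a list or a test of their number. They include Mir143hg (1.92, SE 0.23) with Mir145 (2.34, SE 0.35), whose interval lies inside that of Mir143hg, so that the 2 values can rest on shared reads. Flna (1.23, SE 0.22), Csrp1 (0.91, SE 0.17), Csrp2 (1.47, SE 0.23), Actn1 (0.96, SE 0.17), Npnt (1.94, SE 0.30), Prdm6 (2.04, SE 0.35) and the nitric oxide signalling genes Gucy1a3 (1.10, SE 0.24), Gucy1b3 (0.72, SE 0.14) and Pde5a (1.43, SE 0.22) were higher as well.

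Sost was not lower in the libraries labelled Sost-/- (log2 fold change 1.56, SE 0.48, adjusted p = 0.124). If the groups had been exchanged, the libraries labelled Sost+/+ would hold null animals, yet the lowest of them had 274 Sost counts, which argues against an exchange only if the null allele leaves no Sost reads. Whether Sost follows smooth muscle content was not decided. It lay 0.16 above the median log2 fold change of 17 smooth muscle markers that are not on the cardiomyocyte list. Its log2 ratio to them was -2.97 ± 0.19 and -2.84 ± 1.21 (SD, n = 3, exact two-sided permutation p = 0.9). The rank correlation of Sost with their level was 1 in the libraries labelled Sost+/+ and -0.5 in those labelled Sost-/- (n = 3 each). An exchange therefore stays undecided, since counts are per gene and the allele is not described in the sources used here. Wrong genotypes of single animals, an allele that keeps counted sequence and an effect of the genotype on Sost itself stay open and were not tested.

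The smooth muscle and cardiomyocyte pattern was weighed against tissue makeup. A lower share of cardiomyocyte RNA alone would raise the markers of the other types alike. The median of smooth muscle markers, 1.39, instead exceeded that of endothelial markers, -0.06, by 1.45. A permutation of genes between both lists gave p = 1e-05, the smallest that 100000 permutations can give. Genes of a list move together, so this p does not measure the spread between roots. Mean log2 CPM of the full smooth muscle list was 6.66 ± 0.38 in WT and 7.77 ± 0.20 in KO libraries (SD, n = 3). The endothelial list was at 5.89 ± 0.09 and 5.87 ± 0.28. These values argue against a lower cardiomyocyte share as the whole cause. More aortic wall in the dissected pieces was not decided. Of the 17 smooth muscle markers not on the cardiomyocyte list, 82.4% lay within 1 log2 unit of their median. Myocd (-0.05, SE 0.14), Synpo2 (0.12, SE 0.13) and Notch3 (0.25, SE 0.17) lay further below it and did not pass. Notch3 is also on the pericyte list. Whether other cells of the root express these genes was not examined, so their values cannot decide against more aortic wall. With the smooth muscle score as a covariate edgeR called 0 genes, and the median absolute log2 fold change of the 385 called genes went from 0.83 to 0.41, in a fit whose covariate is tied to the genotype label. Dissection and an effect of the genotype on smooth muscle, its number or its state, both stay open.

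For the clock genes, the fit with the smooth muscle covariate was compared. The median absolute log2 fold change of the 9 called clock genes kept 81.9% of its value (from 1.05 to 0.86, median SE 0.29 with the covariate). This argues against smooth muscle content as the whole cause, in a fit whose covariate is tied to the genotype label. Smooth muscle scores did not overlap between the groups, so the fit with that covariate extrapolates. Of the 9, 9 kept their sign, but so did 362 of the 385 called genes, so the signs decide little. The calls of the clock genes ended in that fit. There the log2 fold change of Per3 went from 1.39 (SE 0.11) to 0.998 (SE 0.25). That of Per2 went from 1.17 to 0.41 (SE 0.37), so that smooth muscle content stays open for Per2. Collection at another time of day is a candidate explanation: in 2 groups of opposite phase, 10 of the Per phase and 5 of the Arntl phase, 100% had the sign it predicts, with medians of 0.95 and -0.70, although many of these signs had been seen before the test and 3 of the 18 clock genes were left out as having no clear phase. Harvest times are not given in the sources used here, and an effect of the genotype on the clock was not tested and stays open.

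Of 10 splits of the 6 libraries into 3 against 3, the genotype split called 385 genes and the highest of the other splits 0. As many lists as in the genotype split, 20, were called in 4 of the 10 splits, that split included, and the highest of the others gave 23. With 10 splits no share under 0.05 is possible for either count. Calls within 10 Mb of Sost had an odds ratio of 1.09; an interval that includes 1 had been fixed beforehand as evidence against flanking sequence of another strain, but was set aside afterwards because the interval reaches 2.20 and leaves the question undecided.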
